A study of Mus musculus with 8 samples.

How the data were processed

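Plasmacytoid dendritic cells (pDC) grown from BALB/c mouse bone marrow with Flt3 ligand were measured on 8 single-colour Agilent arrays, 4 of cells sorted as Sca-1- and 4 of cells sorted as Sca-1+. Per the labels, the cells were obtained by magnetic and flow cytometric sorting, and 100 ng of RNA was amplified and labelled with Cy3 by a low-input kit. The sample descriptions also name an amplified polyA RNA, and how both amplifications relate is not given in the sources used here. Groups and replicate numbers 1 to 4 were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

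Per the file headers, spot intensity on a linear scale was extracted by the authors with Agilent Feature Extraction 10.7.3.1, and probe positions refer to mouse build mm9. The processed intensity deposited for each spot was already background-corrected by that program, per the file headers. Other spot values deposited by the authors were the mean signal, the median local background and the marks for control, outlier, saturated and well-above-background spots. The deposited series value table holds log2 values by the authors, with a median of 3.90 in each of its 8 columns. Its equal quartiles across columns show a between-array quantile step, its columns correlated with the log2 processed signal of their own arrays at 0.998 to 1.00, and 22 of its values are missing. How those missing values arose is not given in the sources used here.

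Each array held 62976 spots, 59305 of them non-control, for 55681 probes. Control spots were left out, as were 105 to 162 outlier spots per array, and 0 spots were saturated. Spots of a probe were averaged on the log2 scale (432 probes were spotted more than once), and each array's 75th percentile of log2 processed signal was subtracted. A level is therefore a log2 signal relative to that percentile, and it does not compare one probe with another. Probe names were updated through the accession for 26582 probes and through a current or older symbol for 3094, and 26005 kept the name in the files. Of the 36095 resulting features, each was read from its probe with the highest mean over all 8 arrays. A gene was tested if that probe was well above background on at least 4 of the 8 arrays, which left 19818 genes. Among called genes, 80 had other detected probes, and 104 of those 107 probes had the same sign as the probe used, with 3 opposite. Whether a probe lies in a coding exon or an untranslated region was not analysed here.

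The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, unpaired), with version 1.17.8 of data.table. Adjusted p-values are Benjamini-Hochberg values over all tested genes, the threshold was 0.05, and no fold limit was set. The 22 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. Camera compares a list with all other tested genes, whereas fry asks whether its genes move, on balance, one way. The groups, the test, the lists, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

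Named genes are Ly6a, the 10 largest rises and 10 largest falls among called genes that were well above background on all 8 arrays with groups that did not overlap, up to 5 lower bounds per direction, the 4 members of each list with the smallest adjusted p, and a fixed set of pDC genes. Clone and locus names were passed over. Ly6c2, one of the fixed set, has no probe by that name and was not analysed here. Genes named to complete a count of 5 or fewer were picked after their values were seen, as were the members given for the fit with the slide as a block. Where a gene was not well above background on any array of 1 group, its fold is a lower bound. The bound sets the bright group's mean against the mean, over the dim group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal.

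Replicate numbers are shared by both groups and, per the file headers, arrays with the same number lay on the same slide. Deviations from the group means correlated within pairs at 0.44, 0.43, 0.64 and 0.89 for replicates 1 to 4. Each lay above the 0.1 set for treating the numbers as pairs. Among replicates 1 to 3, samples with different numbers correlated at 0.12 to 0.54, also above 0.1. That threshold therefore does not tell pairs from other combinations among replicates 1 to 3. Of the 8 samples, 6 correlated best with their own number. The pairing was an alternative (slide as a block), printed beside a result where it changes a call or moves a count by over 1.5 times. On every slide the Sca-1- sample lay at array position 1 and the Sca-1+ sample at position 2, so position and group cannot be told apart by the design. Slides 1 to 3 were scanned on 1 day, and slide 4 on another day with another extraction protocol.

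Both fits were tested on simulated data for this comparison: 19811 genes, 10 runs and 200 changed genes per run. The unpaired fit recovered 0% of 1.5-fold, 5.37% of 2-fold and 62.0% of 4-fold changes, and 1.55% of its calls were false. The fit with the slide as a block recovered 0.299%, 27.5% and 76.5%, and 4.69% of calls were false. A planted shifted list was found in 10 of 10 runs, and an unchanged list was called in 1 of 10. Noise was drawn independently for each gene and list members at random. These runs therefore do not test list calls for genes that vary together. The number of arrays limits the precision of every value. Alternatives were another background correction, between-array scaling, the deposited log2 table, other filters and probe rules, other variance models, stricter thresholds, leaving out arrays, and other list tests. The normexp background correction added an offset of 50 to each spot, while the median processed signal was 11.8 to 23.6 per array. This offset by itself makes differences of dim probes smaller. Results that need genes withheld for evaluation are not reported here, among them 2 of the 20 values set apart within a group and 2 calls gained with the slide as a block.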

Results

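Sca-1, the product of Ly6a, is a membrane-anchored protein of the Ly6 family that is widely used to mark early blood-forming cells. pDC are the dendritic cells that sense nucleic acids through endosomal Toll-like receptors and make type I interferon. The series asks whether Sca-1 separates stages of pDC development whose TLR9 responses differ, and its arrays compare gene expression in 4 Sca-1- and 4 Sca-1+ sorted samples. Between 45.9% and 54.9% of non-control spots were well above background per array. The 75th percentile of processed signal was 262, 171, 234 and 503 in Sca-1- replicates 1 to 4, and 185, 214, 222 and 450 in Sca-1+ replicates 1 to 4. No arrays held identical values.

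Ly6a, the gene behind the sort, was 25.1-fold higher in Sca-1+ pDC (log2 difference 4.65 ± 0.24 SE, adjusted p = 0.000625). Its probe lies on chromosome 15, 74825553 to 74825612 (mm9). The level was 7.43 ± 0.28 (SD, n = 4) in Sca-1+ and 2.78 ± 0.44 (SD, n = 4) in Sca-1- samples. Within slides 1 to 4 the difference was 4.24, 4.72, 4.68 and 4.96. Because Sca-1 chose the groups, this value checks the labels only.

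**Figure D1:**
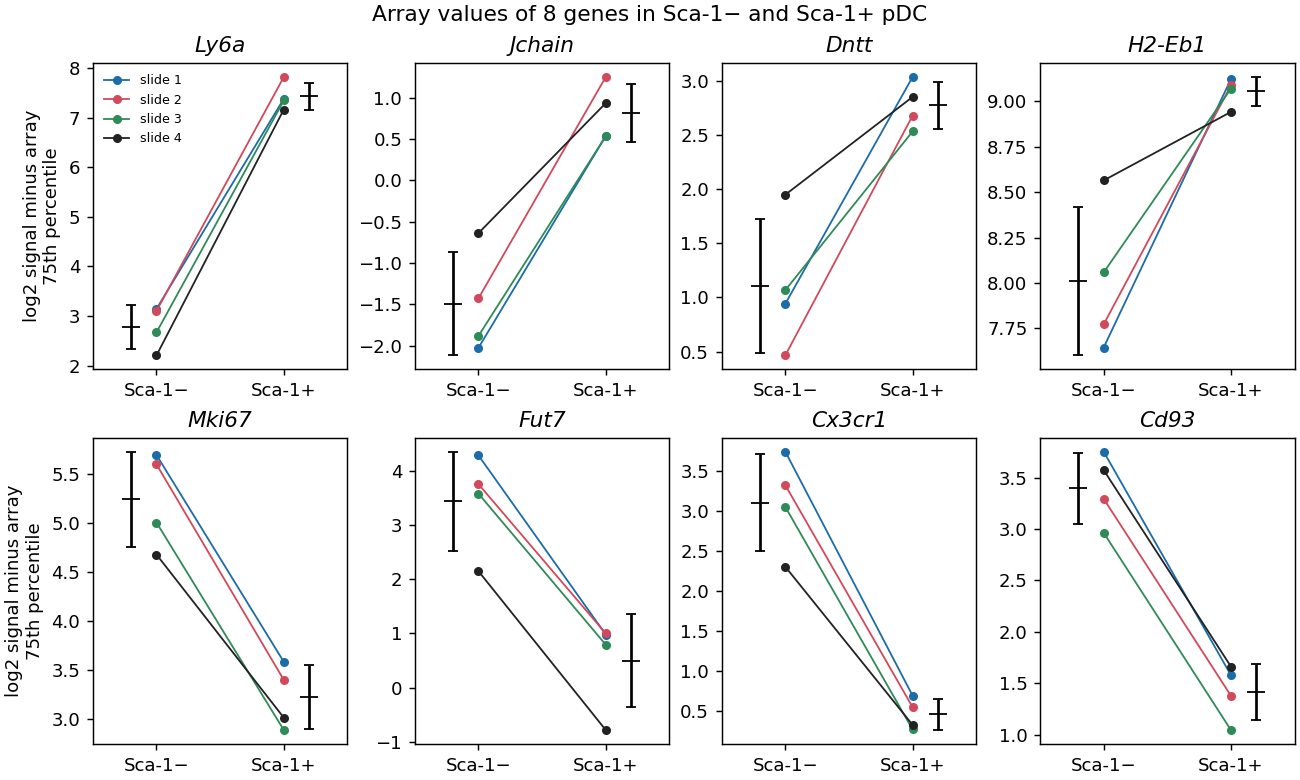
Values of 8 genes on each array (y axis, log2 signal minus the array's 75th percentile) in Sca-1- and Sca-1+ pDC (x axis), with lines joining samples of a slide and black bars giving the mean ± SD (n = 4). Ly6a, Jchain, Dntt and H2-Eb1 were higher in Sca-1+ pDC on all 4 slides, and Mki67, Fut7, Cx3cr1 and Cd93 were lower on all 4.

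Most genes called in the unpaired fit were lower in Sca-1+ pDC (314 of 339). With the slide as a block 817 of 1233 called genes were lower. The largest falls included Fut7, a fucosyltransferase that builds selectin ligands (-2.94 ± 0.54 SE, 7.69-fold, adjusted p = 0.0360), and Cx3cr1, the fractalkine receptor (-2.65 ± 0.29 SE, 6.27-fold, adjusted p = 0.00503). The potassium channel gene Kcnk12 fell by 2.76 on the log2 scale, and Anxa2, encoding a membrane-binding annexin, fell by 2.27. Other leading falls were the kinesin Kif4 (-2.44), the kinase Melk (-2.42), Cdca7 (-2.59), Mxd3 (-2.35), Iqgap3 (-2.31) and the mitotic cyclin Ccnb1 (-2.27). Spp1, encoding osteopontin, was not well above background on any Sca-1+ array and was at least 4.69-fold lower there (adjusted p = 0.00812). Other such bounds were at least 3.08-fold lower for Msantd3, 2.70-fold for the mitotic kinase Aurkb, 2.42-fold for Arhgap31 and 1.63-fold for Mex3a. Normexp background correction ended the calls of these 5 genes and gave differences smaller than the bounds, of -0.90, -0.56, -0.43, -0.48 and -0.24 in that order, and without the filter on dim probes Fut7, Anxa2, Msantd3, Aurkb, Arhgap31 and Mex3a did not pass. Quantile normalization ended those of Anxa2 and Arhgap31. With normexp Kcnk12, Kif4 and Iqgap3 still passed, at -1.73, -1.42 and -1.42. The offset of that correction by itself makes differences of dim probes smaller.

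In all, limma called 339 of 19818 genes, 25 higher and 314 lower in Sca-1+ pDC. Of these, 291 changed at least 2-fold (18 higher, 273 lower). Each of the 339 had the same sign on all 4 slides and groups that did not overlap, which the threshold itself makes likely. Over all tested genes 6.95% had groups that did not overlap, against 2.86% by chance for samples in random order, a value that ignores the pairing by slide. Blocked by slide, the count was 1233 (416 higher, 817 lower), holding 338 of the 339, and the lower share fell to 66.3% from 92.6%. Of 37 called named genes other than Ly6a, 18 to 34 were kept when 1 array was left out. The count was 165, 163 and 205 without Sca-1- replicate 1, 2 or 3, 225 and 176 without Sca-1+ replicate 2 or 3, and 1, 2, 29 and 879 without both samples of replicate 1, 2, 3 or 4.

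Cell cycle genes were lower as a group. Of 38 measured members of the preset list, 33 fell and 0 rose, all 38 differences were negative, and the median was -2.03 (camera adjusted p = 1.51e-71). With an estimated correlation the adjusted p = 0.0796, and fry gave 0.00159. Adjusted over the list alone, 36 were lower. The proliferation marker Mki67 fell by 2.02 (adjusted p = 0.00812), from 5.24 ± 0.48 (SD, n = 4) to 3.22 ± 0.32. Nusap1 (-2.17), Ccna2 (-2.15) and the replication helicase genes Mcm5 (-1.92) and Mcm6 (-1.87) each had an adjusted p of 0.00503. The 5 members that did not pass were Mcm2, Hmmr, Pcna, E2f1 and Tyms. In the fit with the slide as a block only E2f1 and Tyms stayed outside, with differences of -0.20 and -0.28. The list median within slides 1 to 4 was -2.13, -1.97, -2.12 and -1.74.

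**Figure D2:**
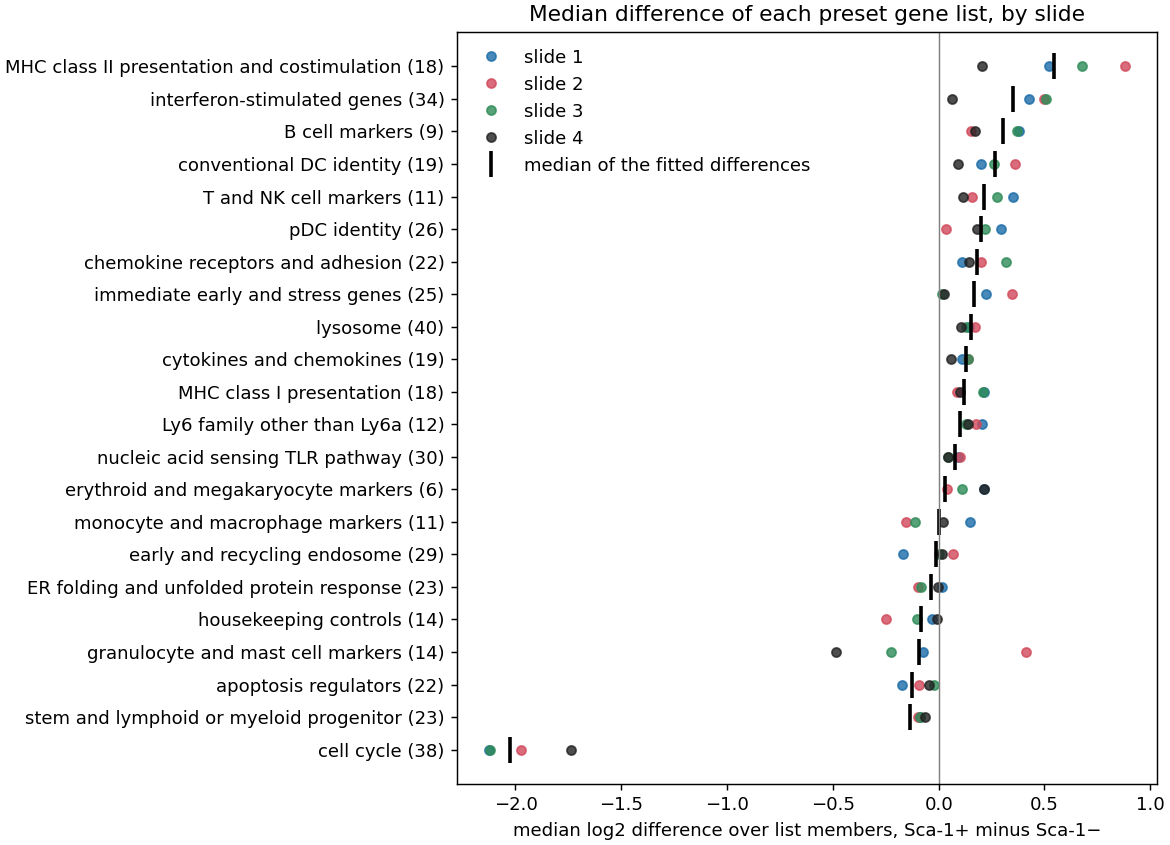
Median log2 difference (x axis, Sca-1+ minus Sca-1-) over the measured members of each of the 22 preset lists (y axis, members in brackets), with coloured points for slides 1 to 4 and black ticks for the median of the fitted differences. The cell cycle list lies at -2.03, whereas the median of MHC class II presentation and costimulation, the highest, is 0.54.

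Fewer genes rose. Jchain, the joining chain of polymeric immunoglobulins, had the largest rise after Ly6a among named genes detected on all arrays (2.31 ± 0.32 SE, adjusted p = 0.00950). Dntt, the polymerase that adds untemplated nucleotides during antigen receptor rearrangement, rose by 1.67 ± 0.30 SE (adjusted p = 0.0314). Further rises were Mgst2, a microsomal glutathione transferase (1.21), Il34, a ligand of the Csf1 receptor (1.16), Ccr6, the Ccl20 receptor (1.04), Duxbl2 (1.02), B3galnt1 (0.91) and the SLAM family gene Slamf9 (0.90). Scaled on the median of detected probes, 10 genes were higher in place of 25, and Dntt, Il34, Ccr6, Duxbl2, B3galnt1 and Slamf9 no longer passed. Testing all genes without the filter on dim probes ended these calls and that of Mgst2, and normexp background correction ended those of Dntt, Ccr6 and Duxbl2. The Slamf9 call also ended with quantile normalization.

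Antigen presentation genes leaned upward. Of 18 measured MHC class II and costimulation genes, 1 rose, the class II beta chain H2-Eb1 (1.05 ± 0.20 SE, adjusted p = 0.0465). Adjusted over the list alone, 6 were higher and 1 was lower, and with the slide as a block 7 passed, H2-Eb1, H2-Aa, H2-Ob, H2-Oa, H2-DMb1, Cd74 and Cd274, all higher. H2-Ab1 differed by 0.83 ± 0.18 SE (adjusted p = 0.0760) and the class II transactivator gene Ciita by 0.90 (adjusted p = 0.0845). The list median was 0.54 (adjusted p = 0.000558, but adjusted p = 0.390 with an estimated correlation). On slide 4 that median was 0.21, against 0.52, 0.88 and 0.68 on slides 1 to 3, and without the filter on dim probes it was 0.30. Of 18 class I presentation genes, 2 rose, H2-Q7 (0.89, adjusted p = 0.0286) and H2-D1 (0.81, adjusted p = 0.0452), or 3 adjusted over the list alone, and H2-M3 joined them in the blocked fit. The class I median was 0.12 (adjusted p = 0.000326, but adjusted p = 0.381 with an estimated correlation). The MHC class I presentation list median was 0.04 with scaling on detected probes, 0.08 without Sca-1- replicate 3 and 0.24 without Sca-1- replicate 4. The H2-Eb1 call ended with quantile normalization or normexp, and all 3 of these calls ended when arrays were scaled on detected probes or no filter was set.

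Tlr9, the receptor for unmethylated CpG DNA, differed by 0.07 (95% confidence interval -0.35 to 0.49) on the log2 scale, and none of the settings fixed beforehand called it. Its chaperone gene Unc93b1 differed by 0.17, the adaptor Myd88 by 0.02 and the endolysosomal transporter Slc15a4 by 0.08. Over those settings Tlr9, Unc93b1 and Myd88 took both signs. Of 30 measured genes of the TLR pathway list, 1 was lower, Spp1, also when adjusted over the list alone (list adjusted p = 0.281). Blocked by slide, Irf7, the regulator of interferon alpha genes, Tlr7 and the protease gene Ctsl passed as higher, and Spp1 and Hmgb1 as lower. The Irf7 difference was 0.94 ± 0.24 SE, with adjusted p = 0.143 unpaired and 0.00606 blocked, and 0.000886 to 0.701 over the settings fixed beforehand. For Tlr7 it was 0.58, with adjusted p = 0.370 unpaired and 0.0460 blocked, and 0.0115 to 1.00 over those settings.

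Interferon-stimulated genes had 30 of 34 positive differences and a median of 0.35 (adjusted p = 7.48e-06, but adjusted p = 0.464 with an estimated correlation). None of them passed singly in limma, also when adjusted over the list alone, although 8 had an unadjusted p under 0.05. In the blocked fit 4 were higher, Oasl1, Oasl2, Ifit2 and Ifi44, and 1 was lower, Gbp3. On slide 4 the median was 0.06, against 0.43, 0.50 and 0.51 on slides 1 to 3. Lysosomal genes had a median of 0.15 over 40 members (adjusted p = 0.00418, but adjusted p = 0.580 with an estimated correlation), with 0 called in limma over all genes or adjusted over the list alone and 4 with an unadjusted p under 0.05. The call for the lysosome list median ended without Sca-1- replicate 2 (adjusted p = 0.0692) or Sca-1+ replicate 4 (adjusted p = 0.318) and with scaling on detected probes (adjusted p = 0.0514). That median ranged from 0.06 to 0.23, the latter without Sca-1- replicate 4, over the settings fixed beforehand. Ctsl alone passed with the slide as a block. Early and recycling endosome genes had a median of -0.01 over 29 members (adjusted p = 0.702), which took both signs over the settings, with 0 called either way and 1 at an unadjusted p under 0.05. Without Sca-1+ replicate 4 the early and recycling endosome list median was called at -0.13 (adjusted p = 0.0337), and with the slide as a block Ehd1, a regulator of endosomal recycling, was lower.

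Genes that define pDC were expressed in both populations. Siglech, a pDC surface lectin, differed by 0.25, Bst2 by 0.20, and the transcription factor genes Tcf4, Spib and Irf8 by 0.06, 0.20 and -0.0048, none of which passed. Over the settings fixed beforehand Siglech ranged from -0.03, without Sca-1- replicate 4, to 0.54 and Bst2 from 0.04 to 0.39, and Tcf4 and Irf8 took both signs. Of 26 pDC identity genes, 1 rose, Dntt, also when adjusted over the list alone, and the list median was 0.20 (adjusted p = 0.00118, but adjusted p = 0.253 with an estimated correlation) and 0.12 with scaling on detected probes. Lag3 and the gut-homing receptor Ccr9 joined Dntt with the slide as a block. None of 19 conventional DC genes passed in limma over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and the list adjusted p was 0.493. In the blocked fit Id2, Itgae and Sirpa were higher, and Zbtb46 and Cd24a lower.

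Progenitor genes moved both ways. Cd93, a surface protein of early progenitors, fell by 1.98 (adjusted p = 0.00503), Sox4, a transcription factor of early lymphoid cells, fell by 1.19 (adjusted p = 0.0155), and Dntt rose. The Sox4 call ended without the filter on dim probes. Cd93, Sox4 and Dntt were the 3 calls among 23 members, with 1 higher and 3 lower when adjusted over the list alone (list median -0.14, adjusted p = 0.184). The stem and lymphoid or myeloid progenitor list median was called at -0.16 with no filter on dim probes (adjusted p = 0.00602) and at -0.15 with every probe on its own (adjusted p = 0.00759), and it ranged from -0.26 to -0.02 over the settings fixed beforehand. Csf1r and Egfl7 were lower with the slide as a block. The probes of Csf1r disagreed, at -1.19 for the probe used and -0.41 and -0.03 for the others. Kit and Flt3, receptors of early progenitors, differed by -0.48 and -0.21, neither passed, and another Flt3 probe lay at 0.10. Kit ranged from -0.75 to -0.15 and Flt3 from -0.45 to -0.02 over the same settings.

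Among 22 chemokine receptor and adhesion genes, Ccr6 rose and Cx3cr1 and Cxcr4 fell, also when adjusted over the list alone. Cxcr4, the receptor that retains cells in bone marrow, fell by 1.10 (adjusted p = 0.00774), a call that ended with scaling on detected probes. The chemokine receptors and adhesion list median did not pass (adjusted p = 0.390), except without Sca-1- replicate 4 (adjusted p = 0.0183). In the blocked fit Ccr9, Itga4 and Itgal were also higher. Of 19 cytokine genes 1 was lower, also when adjusted over the list alone: Il12a, a subunit of interleukin 12, fell by 1.81 (adjusted p = 0.00804) and was well above background on 3 of 4 Sca-1+ arrays (list adjusted p = 0.775). With normexp Il12a still passed, at -0.78. Ccl4 and Il18 were higher with the slide as a block.

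Among 12 other Ly6 family genes 1 rose, Ly6f (4.13 ± 0.54 SE, adjusted p = 0.00779, chromosome 15, 75102462 to 75102522, mm9), also when adjusted over the list alone. It was well above background on 3 of 4 Sca-1- arrays. Ly6a2, which lies between Ly6a and Ly6f (74962205 to 74962264), was at least 11.9-fold higher (adjusted p = 0.00150), with 0 Sca-1- arrays well above background. Normexp background correction kept both calls but gave smaller differences, 2.49 for Ly6f and 1.73, below that bound, for Ly6a2. The list passed with a median of 0.10 (adjusted p = 0.0240, but adjusted p = 0.308 with an estimated correlation). The call for the Ly6 family other than Ly6a list median ended without Sca-1- replicate 1 (adjusted p = 0.0878) or Sca-1+ replicate 4 (adjusted p = 0.103), without replicate 4 in both groups (adjusted p = 0.0600), with camera on ranks (adjusted p = 0.0742), and among genes detected on all 8 arrays (adjusted p = 0.141). That median ranged from 0.02, with scaling on detected probes, to 0.23, with array weights. Ly6c1 (0.56) and Lynx1 (0.50, but 0.09 without Sca-1+ replicate 4) were higher with the slide as a block.

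Of 22 apoptosis regulators 0 passed in limma over all genes, 5 had an unadjusted p under 0.05, and 1 was lower adjusted over the list alone (list adjusted p = 0.194). The apoptosis regulators list median was called with no filter on dim probes (adjusted p = 0.0187). The survival gene Bcl2 differed by -1.41 ± 0.30 SE, with adjusted p = 0.0735 unpaired and 0.00151 blocked, and 0.000183 to 0.510 over the settings fixed beforehand. With the block Tnfsf10, encoding the death ligand TRAIL, was higher. None of 23 endoplasmic reticulum genes (list adjusted p = 0.805) and none of 25 immediate early genes (list adjusted p = 0.493) passed in limma over all genes or adjusted over the list alone, with 1 and 2 at an unadjusted p under 0.05. Btg2 alone of these was higher with the slide as a block.

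Markers of other blood cells gave 0 calls in limma over all genes or adjusted over each list alone. B cell markers had a median of 0.30 over 9 members (adjusted p = 0.0196, but adjusted p = 0.381 with an estimated correlation) and T and NK cell markers 0.21 over 11 (adjusted p = 0.0592, and 0.0335 with the slide as a block, but adjusted p = 0.455 in that fit with an estimated correlation), with 2 and 3 members at an unadjusted p under 0.05. The call for the B cell markers list median ended without Sca-1- replicate 3 (adjusted p = 0.0940), Sca-1+ replicate 2 (adjusted p = 0.0606) or Sca-1+ replicate 4 (adjusted p = 0.0587), and without replicate 3 in both groups (adjusted p = 0.0569). It also ended with scaling on detected probes (adjusted p = 0.0951) or no filter on dim probes (adjusted p = 0.480), and with normexp it was 0.16. The T and NK cell markers list median was called without Sca-1- replicate 4 (adjusted p = 0.0318), without replicate 4 in both groups (adjusted p = 0.0273), with camera on ranks (adjusted p = 0.0224), with the mean over all probes of a gene (adjusted p = 0.0432) and with every probe on its own (adjusted p = 0.0413). It ranged from 0.13 to 0.35 over the settings fixed beforehand. Monocyte and macrophage markers (11 members, adjusted p = 0.702), granulocyte and mast cell markers (14, adjusted p = 0.944), and erythroid and megakaryocyte markers (6, adjusted p = 0.875) did not pass, with 1, 0 and 0 members at an unadjusted p under 0.05. Blocked by slide, Apoe and Fcnb were higher and Csf1r, F13a1 and Prtn3 lower, although the 2 Fcnb probes disagreed, at 0.52 for the probe used and -0.18 for the other. The 14 housekeeping genes had a median of -0.08 (adjusted p = 0.181), with 0 called either way and 2 at an unadjusted p under 0.05. The housekeeping controls list median was called at -0.15 with every probe on its own (adjusted p = 0.000394) and at -0.12 with the replicate block on the deposited value table (adjusted p = 0.0337), and it ranged from -0.25 to -0.01 over the settings fixed beforehand.

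Replicate 4 stood apart from the other arrays. The first principal component held 60.1% of the variance and separated both samples of replicate 4 from the other 6, and the next held 19.6% and separated Sca-1+ from Sca-1- samples. Granulocyte and mast cell markers were lower in replicate 4 than in replicates 1 to 3, by a median of -2.38 in Sca-1+ and -2.22 in Sca-1- samples.

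**Figure D3:**
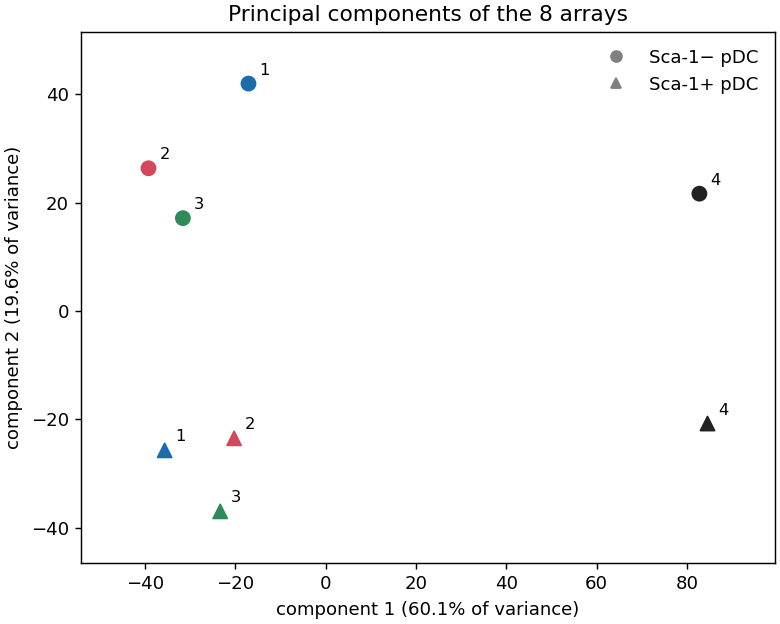
The 8 arrays on the leading pair of principal components (axes, component scores with the percent of variance in brackets), with circles for Sca-1- and triangles for Sca-1+ pDC, coloured and numbered by replicate. Both replicate 4 samples lie apart along component 1 (60.1%), and the groups part along component 2 (19.6%).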

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

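The test of scan day and protocol in this part was chosen only after the result was seen. In groups of 4, a sample was singled out when its gap to the nearest other, divided by the group's range, passed Dixon's 95% critical value. Of 292 groups of values 20 (6.85%) did so, where chance gives about 1 in 20, and in 14 of them the sample apart was replicate 4.

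In Sca-1- pDC, replicate 4 stood apart for Ccr6 (ratio 0.940, level 1.35 against 0.55 to 0.60), Itga4 (0.874, 3.67 against 2.97 to 3.06) and Bcl2 (0.941, 2.00 against at least 3.04). It also did for Siglech (0.864, 8.09 against 9.16 to 9.33), Kit (0.850, 0.29 against -1.10 to -0.89) and the mean of the lysosome list (0.881, 4.85 against 4.48 to 4.53). In Sca-1+ pDC, replicate 4 stood apart for Fut7 (0.883, -0.78 against 0.79 to 1.00), H2-Ab1 (0.941, 8.95 against 9.33 to 9.35), Csf1r (0.925, 2.45 against 3.65 to 3.74) and Unc93b1 (0.855, 7.45 against 6.57 to 6.70). The remaining replicate 4 cases there were Cd5 (0.939), Ermap (0.887) and the 75th percentile of processed signal (0.860). Other samples apart were Sca-1- replicate 3 for Mgst2 (0.939) and replicate 1 for Anxa2 (0.833). In Sca-1+ pDC they were replicate 3 for Ccr6 (0.888) and Nusap1 (0.973), and replicate 2 for Spp1 (0.865).

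Both replicate 4 samples differed at least 2-fold in the same direction from the mean of replicates 1 to 3 for 2666 of 19811 genes, 625 higher and 2041 lower. Array brightness and percentile scaling are argued against as the whole cause, since in the deposited quantile-normalized values the first component still held 55.4% of the variance and separated both samples. Cells of another lineage may contribute: the granulocyte and mast cell list was lower in both groups, with a median difference of -2.38 in Sca-1+ and -2.22 in Sca-1- samples, and 9 of its 14 members, none of them held by another list, were at least 2-fold lower in both. Mcpt8 averaged 2.26 in Sca-1+ and 2.32 in Sca-1- replicates 1 to 3 and lay at -4.27 and -4.09 in replicate 4. Prss34 averaged 2.34 and 2.14 in replicates 1 to 3 against -2.53 and -2.14 in replicate 4. In all, 11 of the 14 were lower in replicate 4 in both groups, so for most members the higher values lay in replicates 1 to 3. S100a8, S100a9 and Lcn2 were lower in Sca-1+ replicate 4 but 0.08, 0.31 and 0.16 higher in Sca-1- replicate 4. All samples were sorted for pDC by magnetic and flow sorting, and how fully this removed such cells was not tested. Scan day and protocol cannot be told apart from a difference between cultures, because each covers whole replicates (the deviations of both samples correlated at 0.892), and apart from other cell lineages no biological explanation was tested.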

How the results depend on the processing

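The fits that block on slide without replicate 4, and on the deposited table, were chosen only after the result was seen. Over 36 settings no result reversed past the threshold, but 42 values of named genes and 31 list medians changed sign, most often those of the monocyte, granulocyte and erythroid lists. Ly6a stayed called, and its difference ranged from 4.46 to 4.78 across fits, with 4.24 within slide 1. Counts below give all called genes, then genes higher in Sca-1+ pDC, then genes lower in Sca-1+ pDC, against 339, 25 and 314. Pairing samples by the replicate block gave 1233, 416 and 817. The same block gave 941, 314 and 627 without replicate 4, and 1244, 443 and 801 on the deposited table. The replicate as a random effect (correlation 0.754) gave 2294, 926 and 1368, and array weights gave 1509, 499 and 1010. In the block fit the median standard error was 0.102 against 0.219. No filter on dim probes, which tests more genes, gave 182, 6 and 176, and the stricter threshold gave 149, 6 and 143. Scaling on the median of detected probes moved the difference of every gene down by the same amount, so the median of all genes was -0.05 in place of 0.03. List medians given for this scaling carry that shift. It left 10 genes higher, and how far the shift accounts for this count was not tested. Leaving out an array or a replicate pair gave 1 to 879 genes, 1 to 264 higher and 0 to 615 lower. The low ends left out replicate 1 or 2 and the high ends replicate 4. Fitted array weights were 0.196 and 0.189 for Sca-1- and Sca-1+ replicate 4, against 1.14 to 3.07 for the other arrays. Replicate 4 thus added most to the spread within groups in the unpaired fit. How far this sets the counts was not tested. Of 37 called named genes other than Ly6a, 37 were kept under the block and 20 with no filter, and 0, 1, 4 and 36 without replicates 1, 2, 3 and 4. Removing single arrays kept 18 to 34.

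Of the preset gene lists past the threshold, 8 in all, 0 passed camera with an estimated correlation and 1 passed fry. Estimated correlations were 0.544 for cell cycle, 0.377 for interferon-stimulated genes, 0.290 for lysosome and 0.267 for MHC class II. They were 0.233 for MHC class I, 0.151 for B cell markers, 0.032 for pDC identity and 0.024 for the Ly6 family. All lay above the preset 0.01, and a larger correlation raises the p-value that camera gives. The correlation does not account for the whole change. For T and NK cell markers it was estimated at -0.0045, below the preset, and the unadjusted camera p still rose from 0.0242 to 0.0560. How much of each lost call the correlation explains was not tested. For fry the cause was not tested. With the slide as a block 8 passed fry: cell cycle, Ly6 family, MHC class I, lysosome, TLR pathway, progenitor, apoptosis and erythroid. Across lists, 658 of 704 values kept their side of the threshold, 31 lost a call and 15 gained one. Among named genes, 2965 of 3439 tested values did, 286 lost and 188 gained a call, and 126 of 476 within-slide values, which have no test, moved by more than the replicate spread. Beyond the block results printed with the gene groups, the pairing changed the camera call of T and NK cell markers and of no other list, and it changed no other call of a named gene reported here. About 1 spot in 2 was well above background (45.9% to 54.9% per array), which limits what dim genes can show.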

Other observations

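In this part, the tests of array position and of another lineage in the Sca-1- sort and all family tests were chosen only after the result was seen. Centromere protein genes were lower in Sca-1+ pDC. The family was chosen by gene symbol alone, not by function. Of 19 measured genes named as centromere proteins, 11 fell and all 19 differences were negative. The median was -1.54 (unadjusted p = 0.00536 with an estimated correlation, limma's camera). With normexp background that median was -0.89, and under the 4 scaling alternatives no family median and no called family member changed sign. Examples were Cenpn (-2.20, with normexp -0.78), Cenpm (-2.08, with normexp -1.16) and Cenpk (-1.82), and 2 of the 19 are also in the cell cycle list. Among 30 kinesins, motor proteins of microtubules, 9 fell, including the mitotic motors Kif18b (-2.21, with normexp -1.23), Kif22 (-2.05) and Kif20b (-1.73), while the family median was -0.11. Of these 30, 3 are in the cell cycle list.

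Replication-dependent histone genes, which are transcribed mainly during DNA synthesis, had a median of -1.15 over 40 genes. None passed in the unpaired limma fit, 12 had an unadjusted p under 0.05, and 23 were lower with the slide as a block (camera unadjusted p = 8.69e-11, and 0.181 with an estimated correlation). By slide the histone median was -0.94, -1.72, -1.23 and -0.52. Whether the amplified polyA RNA held all of these transcripts, and whether each histone probe reads only its own gene, was not tested. The Oas family of interferon-induced sensors of double-stranded RNA had a median of 0.91 over 9 genes (camera unadjusted p = 0.000232, and 0.162 with an estimated correlation). That median was 0.48 with normexp, and 1.05, 0.95, 1.33 and 0.25 within slides 1 to 4. In limma 0 were called, 3 had an unadjusted p under 0.05, and 4 were higher with the slide as a block. Of these genes Oas1a, Oas2, Oas3, Oasl1 and Oasl2 are also in the interferon-stimulated list, so the family is no separate observation. By comparison, 37 proteasome subunit genes had a median of -0.12, with 32 negative, 0 calls in both fits and 1 at an unadjusted p under 0.05 (camera unadjusted p = 0.000218, and 0.167 with an estimated correlation), and 74 ribosomal protein genes had a median of -0.03 and 0 calls in both fits, with 0 at an unadjusted p under 0.05.

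The lower cell cycle list was set against array position, since every Sca-1+ sample lay at position 2. On values without scaling between arrays, 0% of 10000 random lists matched on signal had a median as low, and the lowest random median was -0.22 against -2.11. This argues against position as a shift of all spots of like signal, while an effect of position on single probes cannot be told apart from the group in this design. A large share of differentiated cells of those lineages is also argued against, because the lowest median of the 5 marker lists was -0.093. That median, of granulocyte and mast cell markers, ranged from -0.72 to 0.57 over the settings fixed beforehand. Blocked by slide, Csf1r, F13a1 and Prtn3 were lower, while Apoe and Fcnb were higher. List medians cannot decide on a small share, or on cells outside these lists, in the Sca-1- sort. Cycling progenitors in that sort remain open, as Cd93 and Sox4 were lower, although Dntt of the same list was higher and Kit and Flt3 did not pass. A larger share of dividing cells among Sca-1- pDC may account for the pattern, as a hypothesis that these arrays cannot separate from such progenitors.

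Ly6f and Ly6a2 rose with Ly6a, their neighbour on chromosome 15, and Ly6a RNA binding to their probes is a candidate explanation. The Ly6f and Ly6a2 probes, each of 60 bases, shared 25 and 21 bases with the Ly6a probe in the best ungapped alignment, where 1000 unrelated probes shared a median of 21 and at most 28. The probes can lie on different parts of similar transcripts, and transcript sequences were not analysed here, so binding of Ly6a RNA cannot be told apart from a shared rise of these genes.

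Of 35 splits of the 8 samples into 4 and 4, 1 called as many as 339 genes, the real one, and the highest other gave 1. Those splits ignore the pairing by slide. Only 8 splits part all pairs, too few for a share under 5%, and the highest other among them gave 0. Blocked by slide, the real split gave 1233 and the highest other 0.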
